A study of Homo sapiens with 9 samples.

How the data were processed

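Total RNA was sequenced in bulk from fibroblasts sorted from normal human prostate, with 5 peripheral zone and 4 transition zone libraries. Per the labels' protocols, the same number of sorted cells was used per library, RNA was purified on micro columns, and libraries were made with a stranded total RNA kit. A total RNA kit keeps noncoding and ribosomal RNA. Groups were taken from the zone named in the labels. The transition zone label includes the urethra.

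The values are FPKM, deposited by the authors in 1 table with 1 column per library, with no pooling. The submitters' processing notes name bcl2fastq 2.20, HISAT2, SAMtools, featureCounts, edgeR and the GRCh38 build, with no settings. The annotation release and the way FPKM was computed are not given in the sources used here. Each of the 21268 listed genes exceeds 1 FPKM in at least 1 library (lowest row maximum 1.00), so the table had been filtered before deposit. Of the gene identifiers, 21006 (98.8%) matched GENCODE release 29, from which coordinates were taken. FPKM sums ran from 386165 to 500755 per library.

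Read depth is not known. Low values of short genes repeated at whole multiples of a step within a library, which gives depth only relative to the other libraries. The error of that measure was not estimated. By that measure peripheral zone replicate 4 lay 10.2-fold, peripheral zone replicate 3 5.52-fold and transition zone replicate 4 3.90-fold below transition zone replicate 3, the deepest. The step fitted 83.6% of repeated values in peripheral zone replicate 4 and 82.5% in peripheral zone replicate 3. Genes at 0 gave another order, at 5.35% in peripheral zone replicate 3 and 7.39% in transition zone replicate 4. Other values did not fall on whole reads, so no count test was run. Low genes in shallow libraries are the least precise.

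Values were analysed as log2(FPKM + 1). Genes with at least 1 FPKM in at least 4 libraries were tested (14487, with 6781 left out). The test was limma 3.58.1 in R 4.3.3 with an intensity trend, with zone as the only term, and Benjamini-Hochberg adjusted p under 0.05 as the threshold. A difference is transition zone minus peripheral zone, and a positive value means higher in the transition zone. The test, the gene lists, the rule for named genes and the alternatives named here were set before the data were examined.

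Of 45 gene lists fixed from general knowledge, 38 had at least 5 tested genes. They were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation and with fry, with adjustment over the 38 lists. Members were also adjusted over the list alone. The lists not tested were the sort gate genes (3 genes tested), proliferation genes (4), skeletal muscle markers (1), lymphatic endothelial markers (4), nerve and neuroendocrine markers (1), erythroid and platelet markers (0) and mesothelial markers (4). In 1 case a listed symbol was matched through its Ensembl identifier.

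The rule for named genes took the 12 largest positive and 12 largest negative log2 differences among passing genes that moved the same way in all 4 donors with both zones. It left out clone-based, LOC, LINC, antisense and pseudogene symbols. Where fewer than 12 passed, it was filled with genes passing the donor-blocked fit and then by smallest p, said not to pass. Of each list it took up to 4 passing members or, where none passed, up to 2 of smallest p as values. It always took the sort gate genes and SRD5A2, ESR1, SULT1E1, C7, C3, APOD, WNT2, RORB and LGR5. A few genes that the rule takes are not reported here, and they stayed in the fits and lists.

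The same replicate number marks the same donor, so 4 donors pair the zones. Deviations from the zone means correlated between the 2 libraries of a donor by 0.0415 to 0.442, over 0.1 for 2 of the 4 pairs, and 2 of 4 transition zone libraries correlated best with their own donor. The donor was fitted as a fixed block (3 residual degrees of freedom) and as a random effect, with a correlation of 0.306 estimated over all genes with statmod 1.5.0. Other alternatives changed the pseudocount (0.1 and 0.5), the filter (none, or 5 FPKM), the scaling, the variance trend, the library weights, the threshold and the libraries included. Settings without both replicate 4 libraries, with the basal epithelial score as a covariate, relative to the pan-fibroblast mean, and with the donor block in fry and in camera with an estimated correlation were added after the data were seen.

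The fit was tested on simulated data with the real genes' means and spreads, 14487 genes, 200 changed and 10 runs. It recovered 16.0% of genes changed by 1 on the log2 scale, 70.6% of those changed by 2 and 88.8% of those changed by 3, with 5.05% false calls. The simulated genes and libraries were independent, with no donor pairs and no library apart, so these shares need not hold for the real data. Camera called 100% of simulated lists of 15 genes moved by 1 and 0.909% of unmoved lists, with independent genes. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.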

Results

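Fibroblasts were sorted by flow cytometry from the normal prostates of 5 organ donors, and their RNA was sequenced in bulk. The gland had been dissected into its peripheral zone, the outer glandular region, and its transition zone, which was taken with the urethra. Tissue was digested with collagenase, and the frozen suspensions were thawed and sorted for viable cells positive for podoplanin (PDPN) and negative for EPCAM (CD326, an epithelial surface protein), PTPRC (CD45, on leukocytes) and CD200. The peripheral zone gave 5 libraries and the transition zone 4. Both zones came from the same donor in 4 cases, and peripheral zone replicate 2 had no partner. Each library had a deposited FPKM value (fragments scaled by gene length and by the library total) for 21268 genes. The number of genes above 0 ran from 18904 in peripheral zone replicate 4 to 20821 in transition zone replicate 3. Read totals are not part of the table, so no interval for counting error was computed. Structural and mitochondrial RNA took between 56.4% and 70.9% of a library's FPKM sum. Both replicate 4 libraries carried a ribosomal RNA precursor transcript (FP236383.5) at 21547 and 22992 FPKM, against 157 to 2099 in the others.

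The comparison asked how libraries of sorted cells from the transition zone differ from those of the peripheral zone. RNA of epithelial markers was present in both. The mean log2(FPKM + 1) was 4.51 for pan-fibroblast genes and 5.66 for basal epithelial markers in the peripheral zone. In the transition zone these means were 5.69 and 4.76. The cells that a difference comes from were therefore not identified. In the transition zone, 18 of 14487 tested genes were higher and none was lower. They included MSX2, a homeobox transcription factor of the BMP pathway, at 0.941 ± 0.613 FPKM in the peripheral zone and 10.3 ± 4.94 in the transition zone (SD, n = 5 and 4, as for all FPKM values here). The lipid carrier apolipoprotein E (APOE) went from 6.88 ± 3.23 to 40.9 ± 11.2 FPKM, and AKR1C2, an enzyme that inactivates dihydrotestosterone, from 1.72 ± 1.17 to 17.9 ± 9.94. The secretoglobin SCGB3A1, on the fixed list of club and hillock markers, stood at 0.200 ± 0.248 against 10.005 ± 8.72 FPKM, and the mucin MUC1 at 2.07 ± 0.843 against 13.2 ± 5.54. For SCGB3A1 the means were 0.0951 without peripheral zone replicate 5 and 5.85 without transition zone replicate 4.

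The 18 genes were higher in the transition zone in all 4 donors with both zones. SCGB3A1, KIAA0408, MLC1, GRK5-IT1, AC015908.6, TMEM238L, RNF223 and SGPP2 were under 1 FPKM in every peripheral zone library. The filter of 1 FPKM in at least 4 libraries kept them only through the 4 transition zone libraries. Their direction in the 4 donors was thus fixed by the filter and adds no support. The filter also bears on their calls, since it did not treat higher and lower genes alike. A gene under 1 FPKM in the transition zone needed only 4 of the 5 peripheral zone libraries. With no filter, 1 of the 18 genes passed (21268 genes tested). The limma adjusted p values of the 18 lay between 0.0338 and 0.0489. On the log2(FPKM + 1) scale, which understates changes of low genes, the difference was 2.89 (SE 0.44) for SCGB3A1, 2.75 (SE 0.39) for AKR1C2, 2.61 (SE 0.39) for the adhesion receptor ADGRF1 and 2.49 (SE 0.35) for MSX2. It was 2.48 (SE 0.36) for APOE, 2.17 (SE 0.33) for MUC1, 2.15 (SE 0.32) for the metalloprotease ADAM8 and 1.59 (SE 0.23) for the receptor GPRC5D. KIAA0408, MLC1, GRK5-IT1 and SHF had differences of 1.43, 1.43, 1.42 and 1.41. Outside the rule for named genes, the 6 remaining were LINC01082, AC019349.1, AC015908.6, TMEM238L, RNF223 and SGPP2. The smallest p value belonged to LINC01082, a noncoding transcript with a difference of 2.36 (SE 0.27), from 0.668 ± 0.426 to 7.53 ± 2.204 FPKM. AKR1C2 has near-identical paralogs, so its share of the AKR1C reads is uncertain. AC019349.1 lies opposite to KRT13, and whether the counting used strand is not given in the sources used here. GRK5-IT1 lies within GRK5 and TMEM238L within AC015908.6, each on the same strand, so strand could not part their reads. TMEM238L and AC015908.6 had close means, 0.0845 and 0.0662 FPKM in the peripheral and 1.81 and 1.71 in the transition zone. They may thus be 1 signal counted as 2 genes.

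In GRCh38 coordinates of GENCODE release 29, MSX2 (ENSG00000120149) lies on chromosome 5 from 174724533 to 174730893 and APOE (ENSG00000130203) on chromosome 19 from 44905754 to 44909393. AKR1C2 (ENSG00000151632) lies on chromosome 10 from 4987400 to 5018031, MUC1 (ENSG00000185499) on chromosome 1 from 155185824 to 155192916, and SCGB3A1 (ENSG00000161055) on chromosome 5 from 180590103 to 180591540. LINC01082 (ENSG00000269186) covers positions 86196181 to 86199720 of chromosome 16.

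**Figure D1:**
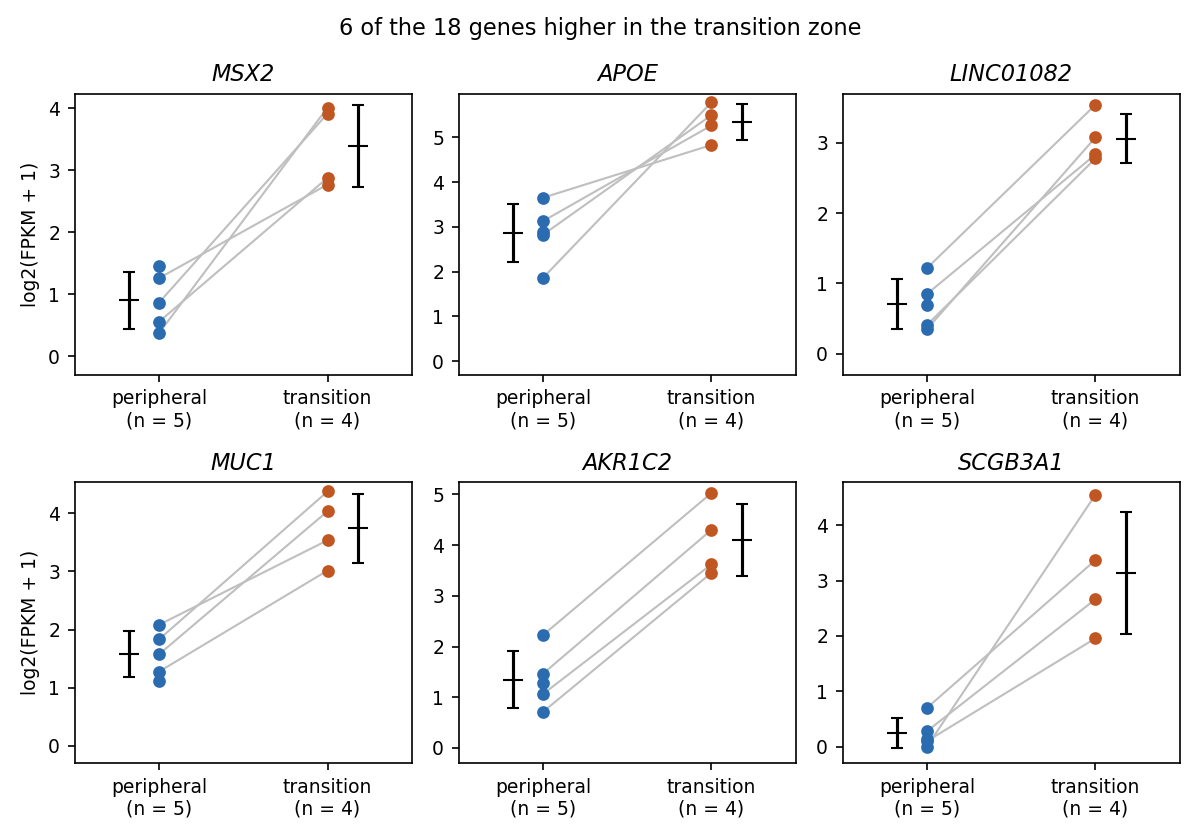
Levels of MSX2, APOE, LINC01082, MUC1, AKR1C2 and SCGB3A1 as log2(FPKM + 1), with 1 point per library, grey lines joining the zones of 1 donor, and black marks for the mean ± SD (n = 5 and 4). All 4 joined pairs rise towards the transition zone for these 6 of the 18 genes. For SCGB3A1, under 1 FPKM in every peripheral zone library, the filter on low values fixed this.

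The calls depended on how the donor was treated. With the donor as a fixed replicate block, none of the 14487 genes passed (lowest adjusted p 0.0673, with 2291 genes at an unadjusted p under 0.05). With the donor as a random effect in limma, 202 passed, 168 higher and 34 lower, and these included all 18. Without a donor term, 1476 genes had an unadjusted p under 0.05, of which 1101 were higher and 375 lower, where independent genes give about 724 by chance and 9 of 100 splits of the libraries gave as many (highest other 2097). Leaving out peripheral zone replicate 1, 2 or 5, or transition zone replicate 1, 3 or 5, gave 0 genes. Leaving out peripheral zone replicate 3 gave 2 (1 of the 18), peripheral zone replicate 4 gave 64 (18 of the 18) and transition zone replicate 4 gave 49 (16 of the 18). Without both replicate 4 libraries, a setting chosen after their ribosomal RNA levels were seen, 72 genes passed, 64 higher and 8 lower, and 15 of the 18 were among them. Scaling by the median ratio gave 12 higher and 4 lower. Values relative to the library's pan-fibroblast mean, also chosen after the data were seen, gave 1 higher and 1202 lower. That setting moves every log2 difference by the same -1.18, so the lower direction follows largely from the subtraction. The replicates come from different donors.

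No gene passed as lower in the transition zone, and the genes of smallest p in that direction are given as values. The endothelins EDN1 and EDN2, vasoconstrictor peptides, stood at 40.6 ± 19.6 against 8.74 ± 4.48 FPKM and 5.31 ± 3.10 against 0.364 ± 0.103. The matrix glycoprotein tenascin C (TNC) stood at 52.5 ± 16.2 against 13.7 ± 6.16, and the metallothioneins MT1E and MT1X at 21.9 ± 9.18 against 4.96 ± 1.66 and 33.6 ± 12.1 against 9.27 ± 4.12. DEFB1, a defensin, and GBP1, an interferon-induced GTPase, had log2 differences of -1.99 and -1.94. USP31, MIR4435-2, VEZT, MIR4435-1 and THBD followed at -1.80, -1.60, -1.36, -1.29 and -0.99. MIR4435-1 and MIR4435-2 are near-identical copies whose reads cannot be assigned with certainty. In limma their adjusted p values ran from 0.0572 for EDN2 to 0.106. All 12 were lower in 4 of 4 donors, and all 12 passed with the donor as a random effect (adjusted p 0.0150 to 0.0323).

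All 12 pan-fibroblast genes were on the transition zone side, with a median log2 difference of 1.07, and 4 rose when adjusted over the list alone. Of these, the growth factor receptor PDGFRA went from 8.01 ± 9.02 to 31.5 ± 13.2 FPKM and the proteoglycan lumican (LUM) from 20.05 ± 19.7 to 68.3 ± 27.3. The list's mean was higher in 3 of 4 donors. Of its 12 genes 8 are also in another list tested, as are 4 of the elastic fibre and proteoglycan genes and 4 of the collagens. Calls of lists that share members are not separate support. Of 26 elastic fibre and proteoglycan genes, 9 rose over the list alone, among them LTBP1, which binds latent TGF-beta (5.46 ± 1.41 against 22.7 ± 7.57), and versican (VCAN, 14.8 ± 8.14 against 65.2 ± 13.5). Of 16 collagens, 6 rose over the list alone, among them COL6A2 (110 ± 27.2 against 293 ± 64.8) and COL14A1 (3.06 ± 1.82 against 22.7 ± 17.4). Matrix proteases and inhibitors had 3 of 25 that rose over the list alone, with MMP2 at 55.3 ± 25.4 against 138 ± 26.8 and MMP14 at 28.1 ± 13.3 against 68.2 ± 24.4. None of these members passed over all genes tested. Means moved by over 1.5 times for PDGFRA without peripheral zone replicate 2 (4.05), LUM without peripheral zone replicate 4 (11.5) and COL14A1 without transition zone replicate 1 (14.7). In the same libraries the mean log2(FPKM + 1) of basal epithelial markers was 5.66 in the peripheral and 4.76 in the transition zone, and that of luminal markers 4.06 and 2.83.

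By camera with its preset correlation of 0.01, the adjusted p was 4.13e-06 for the pan-fibroblast list and 4.00e-09 for the elastic fibre list. It was 9.04e-06 for the collagens and 0.000928 for the proteases. All 4 calls were lost with an estimated correlation, at an adjusted p = 0.316 for the first 3 lists and an adjusted p = 0.356 for the proteases. The same held for every list: 22 of 38 were called with the preset correlation, 15 higher and 7 lower, and 0 with an estimated correlation or by fry, both without a donor term. The lowest adjusted p values were then 0.264 and 0.0652. With the donor as a fixed replicate block, fry called 4 lists, steroid receptor targets (0.0102) and blood endothelial markers (0.0325) lower and growth factors (0.0325) and retinoid genes (0.0447) higher, and camera with an estimated correlation called 0. With the mean of the basal epithelial markers as a covariate, chosen after the data were seen, the adjusted p was 0.0481, 0.00180 and 0.00950 for the pan-fibroblast, elastic fibre and collagen lists, and the proteases lost the call (0.489, median 0.55 against 0.64 without it).

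Epithelial markers lay on different sides by type, although EPCAM-positive cells had been sorted out. Of 15 markers of urethral club and hillock cells, which line the urethra and proximal ducts, 9 rose over the list alone, 1 of them (SCGB3A1) also over all genes tested. The list's median log2 difference was 1.66. Chosen after their values were seen, KRT13 stood at 28.95 ± 20.2 against 198 ± 113 FPKM, KRT4 at 1.65 ± 0.969 against 9.05 ± 4.86, and the immunoglobulin transporter PIGR at 2.77 ± 2.65 against 40.9 ± 36.9. All 9 were higher in 4 of 4 donors. KRT13 lies on chromosome 17 from 41500981 to 41505705. The camera adjusted p was 1.01e-07, and the adjusted p = 0.264 with an estimated correlation.

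Luminal and basal epithelial markers lay on the peripheral zone side. All 16 luminal markers were lower in the transition zone, with a median log2 difference of -1.15, and 1 fell over the list alone. That was MSMB, a secretory protein of prostate luminal cells, which went from 88.1 ± 51.6 to 20.3 ± 11.4 FPKM. HOXB13, a prostate homeobox factor also counted among the HOX genes, stood at 2.63 ± 1.59 against 0.616 ± 0.515. Of 12 basal markers, 10 were lower, and keratin 5 (KRT5, 284 ± 96.7 against 101 ± 44.5) fell over the list alone. KRT14 stood at 126 ± 73.9 against 28.6 ± 31.4, and KRT17, chosen after its values were seen, at 701 ± 325 against 259 ± 125. The mean of KRT14 was 13.7 without transition zone replicate 3 and that of HOXB13 0.361 without transition zone replicate 5. Both list means were lower in 4 of 4 donors. The camera adjusted p was 7.11e-09 for luminal and 8.53e-06 for basal markers, and the adjusted p = 0.316 and 0.356 with an estimated correlation. With the basal covariate the luminal median was -0.55.

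**Figure D2:**
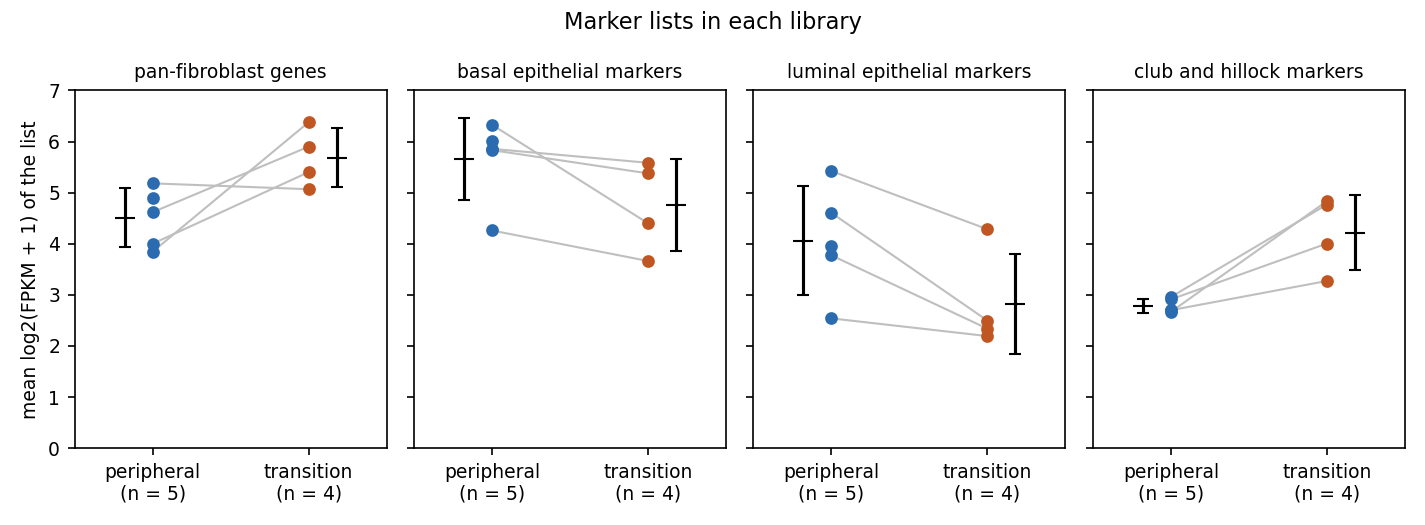
Mean log2(FPKM + 1) of 4 marker lists, with 1 point per library, grey lines joining the zones of 1 donor, and black marks for the mean ± SD (n = 5 and 4). Pan-fibroblast genes averaged 4.51 in the peripheral and 5.69 in the transition zone, club and hillock markers 2.79 and 4.22, basal markers 5.66 and 4.76, and luminal markers 4.06 and 2.83.

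All 17 blood endothelial markers were on the lower side, with a median of -0.50, and none fell over the list alone. With the basal covariate, which moved the median of all genes by 0.19, the endothelial median was -0.04 (camera adjusted p 0.0143), and with the replicate block it was -0.36. The angiopoietin receptor TEK stood at 2.88 ± 0.952 against 1.38 ± 0.522 FPKM and PLVAP at 56.1 ± 19.7 against 28.6 ± 8.81. Schwann cell markers (9 of 15 lower, S100B 6.33 ± 7.71 against 0.898 ± 0.610, CDH19 2.73 ± 1.64 against 0.956 ± 0.755) and pericyte markers (8 of 12 lower, RGS5 15.5 ± 6.95 against 6.71 ± 4.41, NDUFA4L2 2.35 ± 0.404 against 1.22 ± 0.996) had no member past the threshold over the list alone. Without peripheral zone replicate 5 the mean of S100B was 3.03 (log2 difference -0.90 against -1.42 with it). The means of CDH19 without transition zone replicate 1 and of NDUFA4L2 without transition zone replicate 3 were 0.591 and 0.762, and without transition zone replicate 4 the log2 difference of NDUFA4L2 was -0.44 against -0.70 with it. All 13 mitochondrially encoded genes were lower, with a median of -0.36 and MT-ND3 at 501 ± 138 against 279 ± 50.4 and MT-ATP6 at -0.67 on the log2 scale. Camera adjusted p values were 1.44e-06, 0.0181, 0.0224 and 0.000498. With an estimated correlation these were an adjusted p = 0.368, 0.590, 0.388 and 0.491. The Schwann cell call was lost without peripheral zone replicate 3 or 5 or transition zone replicate 4 or 5 (adjusted p 0.0808, 0.101, 0.0928 and 0.0517). The pericyte call was lost without peripheral zone replicate 4 or transition zone replicate 4 or 5 (adjusted p 0.0773, 0.113 and 0.0603). With the basal covariate, Schwann cell, pericyte and mitochondrial lists lost the call (0.343, 0.0534 and 0.166, with medians of 0.19, -0.01 and 0.02), and without both replicate 4 libraries so did the pericyte list (0.152).

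Of 15 complement genes, 8 rose over the list alone, with the C1 inhibitor SERPING1 at 48.5 ± 18.7 against 147 ± 46.5 FPKM. In the BMP and TGF-beta pathway 4 of 32 rose over the list alone, including the activin antagonist follistatin (FST, 3.76 ± 1.72 against 18.9 ± 7.21) and GDF15 (14.4 ± 6.41 against 69.5 ± 30.6). Among 33 growth factors 3 rose over the list alone, including hepatocyte growth factor (HGF, 2.52 ± 1.41 against 11.5 ± 4.04) and IGF2 (21.4 ± 12.3 against 67.3 ± 23.1). The prostaglandin pathway had 4 of 15, with the synthase PTGES at 2.60 ± 2.23 against 10.4 ± 2.96 and the degrading enzyme HPGD at 1.59 ± 1.65 against 15.8 ± 14.0. The means of HPGD were 0.875 and 9.496 without replicate 5 of each zone, and that of PTGES 1.65 without peripheral zone replicate 4. The camera adjusted p was 1.93e-05 for complement and 0.000498 for each of the other 3 lists. With an estimated correlation it was an adjusted p = 0.316, 0.356, 0.316 and 0.264. With the basal covariate the BMP and TGF-beta and the prostaglandin lists lost the call (adjusted p 0.0849 and 0.0769), with medians of 0.70 and 0.56 against 0.54 and 0.66 without it. Basal and luminal epithelial means were lower in these transition zone libraries (4.76 against 5.66 and 2.83 against 4.06).

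Of 11 steroid hormone receptor and metabolism genes, 3 rose over the list alone, AKR1C2 also over all genes tested. Of 40 patterning transcription factors, 5 rose over the list alone, with MSX2 also over all genes tested. Retinoid genes had 3 of 16 that rose and 1 that fell over the list alone, with the binding protein CRABP2 at 17.2 ± 5.86 against 43.3 ± 8.83 FPKM and RBP7 at 2.54 ± 1.16 against 0.637 ± 0.392. Hypoxia and glycolysis genes had 3 of 25, with hexokinase 2 (HK2) at 1.498 ± 0.534 against 14.0 ± 8.70 and PFKFB4 at 0.309 ± 0.0874 against 1.73 ± 0.432. Of 18 steroid receptor target genes 13 were lower. MT1X was the 1 that fell over the list alone, and GREB1 stood at 2.16 ± 1.46 against 0.722 ± 0.250. Of these 18 genes 7 are also in another list tested. In the same libraries the mean log2(FPKM + 1) of luminal markers was 4.06 in the peripheral and 2.83 in the transition zone. The camera adjusted p values of these 5 lists were 0.00122, 0.0162, 0.0258, 0.0181 and 0.000464. With an estimated correlation they were an adjusted p = 0.316, 0.491, 0.493, 0.540 and 0.264. The patterning call was lost without peripheral zone replicate 1 (adjusted p 0.0909) and with the basal covariate (0.0849, median 0.65 against 0.58 without it). The retinoid call was lost without peripheral zone replicate 1 or 4 or transition zone replicate 5 (0.0754, 0.0975 and 0.0611), and the hypoxia call without peripheral zone replicate 5 or transition zone replicate 1 (0.0659 and 0.0580).

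Of 12 genes reported to mark prostate fibroblast subtypes, 4 rose over the list alone. These were complement C3 (18.3 ± 10.5 against 115 ± 131 FPKM), factor D (CFD, 26.1 ± 17.7 against 113 ± 68.6), STC1 (68.4 ± 34.8 against 168 ± 38.2) and WNT2 (1.41 ± 1.25 against 4.72 ± 2.01). C7 and APOD stood at 57.0 ± 44.1 against 138 ± 145 and 454 ± 212 against 726 ± 263, and RORB at 2.66 ± 2.38 against 2.95 ± 1.88. Without transition zone replicate 1 the transition zone means of C3 and C7 were 49.7 and 66.2, and their log2 differences were 1.54 and 0.57 against 2.202 and 1.17 with it. Means also moved by over 1.5 times for ACKR3 without transition zone replicate 1 (19.3), SFRP2 and WNT2 without peripheral zone replicate 4 (4.71 and 0.896) and RORB without peripheral zone replicate 2 (1.68). The camera adjusted p was 0.00132, and the adjusted p = 0.316 with an estimated correlation. The call was lost with the basal covariate (adjusted p 0.213, median 0.87 against 1.21 without it), and basal and luminal marker means were lower in these transition zone libraries (4.76 against 5.66 and 2.83 against 4.06). Adventitial fibroblast genes had 2 of 14 that rose over the list alone, SFRP2 (7.63 ± 7.12 against 28.2 ± 6.31) and ACKR3 (8.15 ± 4.49 against 29.01 ± 19.7). That list's camera adjusted p was 0.0156. It was lost with the replicate block (adjusted p 0.0930, median 1.15 against 1.07 without it), with the basal covariate (adjusted p 0.0849, median 0.94), with an estimated correlation (adjusted p = 0.381) and without transition zone replicate 1 (adjusted p 0.0939). Of the 12 subtype genes 7 are also in another list tested, and of the 14 adventitial genes 7, so these calls are not separate support. SULT1E1 and LGR5 were not analysed here.

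**Figure D3:**
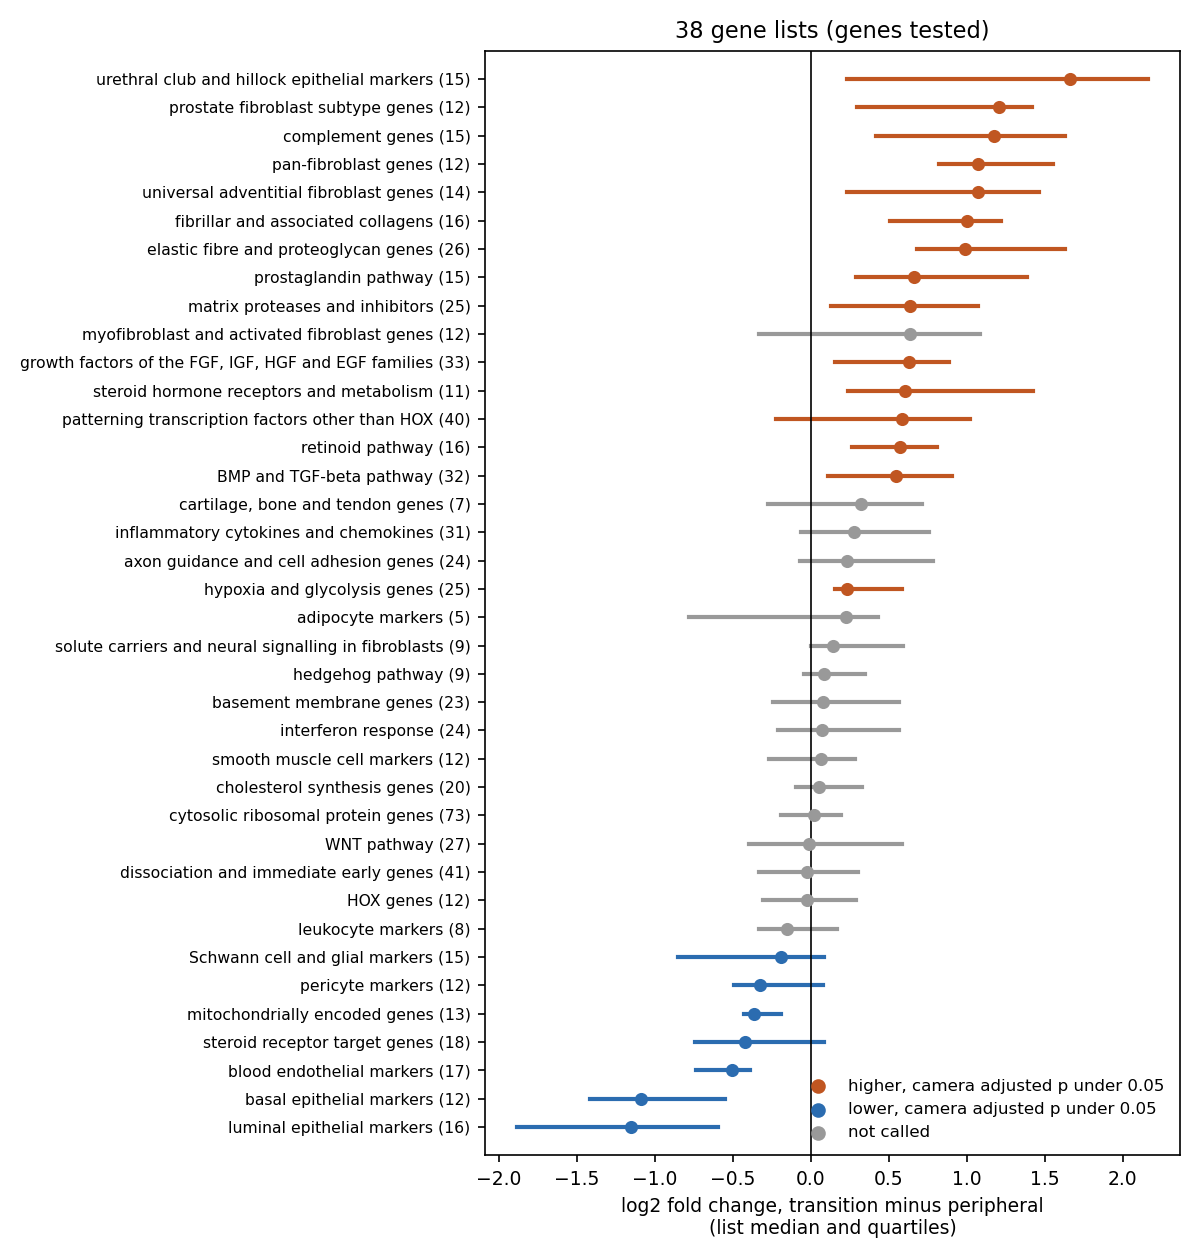
Log2 fold change, transition minus peripheral zone, for 38 gene lists, with the median as a point, the quartiles of the list's genes as a line and the number of genes tested in brackets. Orange lists (15) were called higher and blue lists (7) lower by camera with the preset correlation, and none with an estimated one.

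Estrogen receptor 1 (ESR1) and the 5-alpha-reductase SRD5A2 did not pass. ESR1 stood at 0.960 ± 0.593 against 1.17 ± 0.618 FPKM and SRD5A2 at 3.27 ± 1.58 against 3.05 ± 2.10. Of the genes behind the sort gate, EPCAM stood at 2.68 ± 1.16 against 1.46 ± 0.497, CD200 at 15.1 ± 9.59 against 7.93 ± 2.34 and PDPN at 14.97 ± 14.9 against 24.1 ± 16.2, with limma adjusted p values of 0.554, 0.838 and 0.790. PTPRC was below the filter, at 0.240 ± 0.0665 against 0.957 ± 1.45, where the transition zone mean was 0.235 without replicate 3. Without peripheral zone replicate 4 the PDPN mean was 8.42, and without transition zone replicate 5 the SRD5A2 mean was 2.01.

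The other 16 lists were not called, with camera adjusted p values from 0.189 to 0.950. Some of these lists were called by camera under other settings, given below. Several held members on both sides. Of 12 myofibroblast and activated fibroblast genes, COMP and CDH11 rose and TNC and TAGLN fell over the list alone, and TAGLN was also the 1 of 12 smooth muscle markers that fell. CDH11 stood at 8.46 ± 6.69 against 33.003 ± 14.8 FPKM, TAGLN at 57.7 ± 18.2 against 22.5 ± 9.63, and COMP at 1.08 ± 0.754 against 6.17 ± 4.56. Of 24 interferon response genes, OAS1 rose (1.61 ± 0.853 against 15.7 ± 11.7) and GBP1 fell over the list alone. The WNT pathway had 3 of 27 that rose and 1, SFRP5, that fell (6.68 ± 3.91 against 1.55 ± 1.26). Cartilage, bone and tendon genes had COMP higher and THBS4 lower (2.85 ± 1.60 against 0.709 ± 0.751) over the list alone. PPARG among 5 adipocyte markers, NID2 among 23 basement membrane genes and PDGFRA among 9 solute carrier and neural signalling genes were the single members that rose over their lists. Without transition zone replicate 1 the means of COMP, SFRP5 and THBS4 were 3.95, 0.938 and 0.340.

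The remaining lists had no member past the threshold over the list alone. Among 31 cytokines and chemokines, CCL2 stood at 458 ± 105 against 213 ± 92.5 FPKM and SAA1 at 4.72 ± 2.99 against 0.932 ± 0.311. Camera called that list higher without peripheral zone replicate 4 (adjusted p 0.0157) or transition zone replicate 5 (0.0348). Among 41 dissociation and immediate early genes, NR4A2 stood at 31.8 ± 8.13 against 56.7 ± 10.2 and CCN1 at 309 ± 92.3 against 162 ± 42.5. Relative to other genes, camera called that list lower without peripheral zone replicate 1 (adjusted p 0.0256) and with the basal covariate (0.0419). Among 24 axon guidance genes EPHA7 stood at 1.51 ± 0.882 against 4.01 ± 1.30, among 9 hedgehog genes SHH at 0.768 ± 0.811 against 2.78 ± 1.49 and GLI3 at 0.666 ± 0.526 against 2.84 ± 1.76, and among 12 HOX genes HOXD13 at 2.27 ± 1.14 against 5.21 ± 0.927. Relative to other genes, camera called the axon guidance list higher with no filter (adjusted p 0.0307) and with values relative to the pan-fibroblast mean (0.0103). Leukocyte markers (8 tested, CD68 19.97 ± 4.25 against 27.7 ± 11.7 and C1QC 1.48 ± 1.20 against 0.728 ± 0.747) did not pass. Neither did 20 cholesterol synthesis genes (LSS 4.02 ± 1.65 against 10.9 ± 6.56, INSIG1 31.9 ± 5.30 against 46.6 ± 13.8) or 73 cytosolic ribosomal protein genes (RPL23 21.7 ± 4.47 against 50.8 ± 24.6, RPL12 36.8 ± 15.2 against 68.8 ± 27.98). Relative to other genes, camera called the ribosomal protein list lower with scaling without structural RNA (adjusted p 0.0371) and with library weights (0.0266). It did so too without peripheral zone replicate 3 (0.0299) or transition zone replicate 1 (0.00272) and with the basal covariate (0.00525). Without 1 library the means of SHH (peripheral zone replicate 1), GLI3 (peripheral zone replicate 2) and C1QC (transition zone replicate 5) were 0.408, 0.443 and 0.399. Log2 differences of other values-only members were 0.71 for HSPB6 (1.10 without transition zone replicate 4), -0.78 for LIPE and 1.03 for SLC7A2.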

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

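Tests of the fibroblast list without both replicate 4 libraries and of the opposite movement of the epithelial lists were chosen after the result was seen. Each named gene and each library measure was examined within its zone for a library far from the rest, on the log2 scale used in the test for genes. Of 210 groups examined 11 met Dixon's criterion, where chance gives about 1 in 20, or 10.5.

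In the peripheral zone, replicate 4 was low for USP31 (5.23 FPKM against 15.6 to 18.2, gap 0.871 of the range) and KRT5 (123 against 264 to 354, gap 0.720). The same library was high for MT-RNR1 (10375 FPKM against 84.5 to 143, gap 0.890), for the ribosomal RNA precursor FP236383.5 (21547 against 157 to 487, gap 0.770) and for the percentage of genes listed at 0 (11.1% against 3.56% to 5.35%, gap 0.764). Peripheral zone replicate 1 was high for SHH (2.21 FPKM against 0.261 to 0.506, gap 0.810). In the transition zone, replicate 4 was low for SFRP2 (18.8 against 30.7 to 32.0, gap 0.921), CCN1 (99.8 against 172 to 191, gap 0.836), SAA1 (0.466 against 1.08 to 1.09, gap 0.986) and CD200 (4.49 against 8.65 to 9.67, gap 0.849). Transition zone replicate 3 was high for EDN2 (0.518 against 0.305 to 0.327, gap 0.889).

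Both replicate 4 libraries stood apart from the other 7 on the first principal component, which held 34.7% of the variance. If ribosomal RNA acted only by taking up the total, rescaling by the median ratio would close the gap, but the gap was then 265% of the range of the other 7, against 204% before. If the noise of low values in shallow libraries were the cause, genes with a mean of at least 50 FPKM (595 genes) would not show the gap, and there it was 234%. The first test argues against ribosomal RNA taking up the total as the whole cause. Genes of the second test were picked by the mean over all libraries. They include FP236383.5 and MT-RNR1, both high in replicate 4, which can widen the gap. The second test is therefore weaker evidence against the noise of low values as the whole cause. RNA quality, processing of that donor's tissue and the donor's own biology stay open, and the design, with 1 donor, cannot part them. High MT-RNR1 was not confined to that donor. In transition zone replicate 3 it was 5695 FPKM against 106 in the same donor's peripheral zone library, and FP236383.5 was 2099 against 487. Transition zone replicate 3 did not stand apart on the first component.

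Fibroblast genes were higher and basal and luminal epithelial genes lower in the transition zone by camera with the preset correlation, in cells sorted against EPCAM, but no list call held with an estimated correlation (adjusted p = 0.316, 0.356 and 0.316) and no member of these lists passed over all genes. A larger fibroblast share at the cost of all other cell types alike would lower the club and hillock markers with the basal ones. Instead, over the 4 donors with both zones, club and hillock markers moved above basal markers by a mean of 2.22 on the log2 scale (SD 0.607, 4 of 4 donors). The exact sign-flip permutation p was 0.125, the smallest that 4 donors allow. So the lists did not fall together in these libraries. Both directions were known when this contrast was chosen, so it is not a separate test of that cause. The 2 replicate 4 libraries as the cause are argued against, since without them the median pan-fibroblast difference was 138% of its value with them. With the basal score as covariate 93.9% of the median pan-fibroblast difference was left (camera adjusted p 0.0481, against 4.13e-06 without it, while 9 other list calls were lost). The covariate also raised the median of all genes from 0.09 to 0.28, so this percentage overstates what was left relative to other genes. The percentage lay between the bounds set for and against basal epithelial RNA as the cause. That cause cannot be told apart from the zone, because the score itself differs by zone. A zone difference within fibroblasts stays open, as untested.

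Club and hillock epithelial genes were higher in the transition zone, which was taken with the urethra, by camera with the preset correlation but not with an estimated one (adjusted p = 0.264) or by fry (0.0669), and 1 of 15 passed over all genes. Basal markers did not share the gain. Their mean change was -0.813 on the log2 scale (SD 0.755, lower in 4 of 4 donors, exact sign-flip permutation p = 0.125), 2.22 below that of the club and hillock markers. That direction was known when the contrast was chosen, so it is not a separate test of a general gain of epithelial RNA. RNA of urethral club and hillock cells may be the source, although the sort took podoplanin-positive, EPCAM-negative cells and EPCAM stood at 1.46 ± 0.497 FPKM in the transition zone. With zone means taken out, the 15 genes varied together at percentile 93.1 of 10000 random lists matched on mean level, short of the percentile of 95 set beforehand, so that source cannot be told apart from expression by the sorted fibroblasts. The most abundant were KRT19 (226 ± 87.6 FPKM in the peripheral and 270 ± 114 in the transition zone, not past the threshold over the list alone), KRT13 (28.95 ± 20.2 and 198 ± 113) and AQP3 (37.6 ± 14.95 and 117 ± 29.2). None of the 15 is in another of the 38 lists tested, but KRT19 is also in the mesothelial list, which was not tested.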

How the results depend on the processing

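The settings without both replicate 4 libraries, with the basal score, relative to the pan-fibroblast mean and with the donor block in fry and in camera's estimated correlation were chosen after the result was seen, and the cause of each change below was not tested except where named. The 18 zone genes kept their direction in every setting that tested them (7 of them with the filter of 5 FPKM). Counts stayed within 1.5 times the 18 with a pseudocount of 0.5 (19, of them 1 lower), median ratio scaling (16, of them 4 lower), robust eBayes (15) and a 2-fold minimum (18). They fell to 0 with a pseudocount of 0.1, to 1 with no filter, to 0 with the filter of 5 FPKM (5827 genes tested), to 7 with quantile normalization, to 1 with scaling without structural RNA and to 1 without the trend. They rose to 232 (38 lower) with library weights and to 76 (8 lower) at an adjusted p under 0.1. Leaving out 1 library gave 0 to 64 genes (0 to 13 lower) and 20 to 22 lists. Without both replicate 4 libraries there were 72 (8 lower), and 124 (14 lower) with the donor as a random replicate block. With the basal score there were 32, and relative to the pan-fibroblast mean 1203 (1202 lower). These last 2 settings moved the median of all genes by 0.19 and -1.18, quantile normalization by -0.11 and scaling without structural RNA by -0.16.

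With the replicate block as a fixed donor term 0 genes passed, as a random effect 202 (34 lower) and with library weights 55 (8 lower), and 0 passed with only the donors of both zones and no block. By camera with the preset correlation the fixed block ended the adventitial list's call (adjusted p 0.0930), as did the block with weights (0.0849), and the fixed block changed no other list's call. By fry the fixed block called 4 lists against 0 without it, and by camera with an estimated correlation 0. SRD5A2 turned from -0.10 to 0.0294 with the fixed block, 0.30 with block and weights, and 0.0294 with only the donors of both zones. Lists are given as the mean z of members minus that of other genes. With the fixed block, the random block, block and weights, and only both-zone donors, cholesterol genes turned from 0.0178 to -0.0812, -0.0156, -0.202 and -0.0820. With fixed block and block with weights, cartilage genes turned from 0.0941 to -0.0691 and -0.161, and interferon genes from -0.0304 to 0.00159 and 0.0320.

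The 22 lists fell to 0 with camera's estimated correlation and to 0 by fry without the donor, and were 15 to 24 by camera with the preset correlation. Hypoxia and Schwann cell lists lost the call with the filter of 5 FPKM (adjusted p 0.260 and 0.451) and pericyte markers with weights (0.0915). The basal score ended 9 list calls, namely proteases (0.489), Schwann cell (0.343), fibroblast subtypes (0.213), mitochondrial (0.166), adventitial (0.0849), BMP and TGF-beta (0.0849), patterning (0.0849), prostaglandin (0.0769) and pericyte (0.0534). It added 2 calls, cytosolic ribosomal protein (0.00525) and dissociation genes (0.0419), both lower relative to other genes. For the lists that lost the call, medians are given next. Medians rose for BMP and TGF-beta (0.54 to 0.70) and patterning (0.58 to 0.65), were smaller for proteases (0.64 to 0.55), subtypes (1.21 to 0.87), adventitial (1.07 to 0.94) and prostaglandin (0.66 to 0.56), and went from -0.36 to 0.02 (mitochondrial), -0.33 to -0.01 (pericyte) and -0.19 to 0.19 (Schwann cell). Of 3455 comparisons 69 reversed, in 4 genes and 10 lists, 0 of them called in either fit. SRD5A2 turned to 0.0833 with weights, 0.16 without both replicate 4 libraries and 0.17 with the random block as well, and ranged from -0.417 to 0.0698 without 1 library. RORB (0.21) ranged from -0.0603 to 0.524 without 1 library. With the basal score CD200 turned from -0.54 to 0.39 and PDPN from 0.72 to -0.26. Without 1 library CD200 ranged from -1.09 to -0.270 and PDPN from 0.334 to 1.27. Without 1 library, lists ranged from -0.373 to 0.0303 (adipocyte, -0.152 with all libraries), -0.0193 to 0.232 (basement membrane, 0.0991), -0.256 to 0.236 (cartilage), -0.166 to 0.238 (cholesterol), -0.519 to 0.0408 (dissociation, -0.278), -0.0763 to 0.694 (inflammatory, 0.158), -0.124 to 0.0907 (interferon), -0.840 to 0.0643 (leukocyte, -0.552), -0.0652 to 0.431 (myofibroblast, 0.250) and -0.701 to 0.324 (smooth muscle, -0.389). Without both replicate 4 libraries, and then with the random block too, values were -0.0379 and -0.0460 (cartilage), -0.128 and -0.147 (cholesterol), 0.0722 and 0.0880 (dissociation), 0.0669 and 0.0695 (interferon), 0.147 and 0.143 (leukocyte), and 0.252 and 0.265 (smooth muscle). With the basal score they were -0.600 (inflammatory), 0.0745 (interferon) and 0.0289 (smooth muscle). Relative to the pan-fibroblast mean they were 0.154 (adipocyte) and 0.0845 (interferon). With no filter they were -0.188 (cartilage) and 0.186 (interferon), with the filter of 5 FPKM -0.426 (myofibroblast), with weights 0.0658 (interferon), with the median ratio -0.00119 (basement membrane) and -0.00196 (cholesterol), and without structural RNA 0.0228 (adipocyte) and -0.0213 (cholesterol). Read depth is not in the table, so the precision of low genes in the shallow libraries could not be computed.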

Other observations

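The test of the FOXF1 region and the settings with a basal score and with values relative to the pan-fibroblast mean were chosen after the result was seen. With the basal epithelial score as a covariate, 32 genes passed, all higher in the transition zone, against 18 without it. They held 13 of the 18 and 19 others, of which the following were chosen after their values were seen. They were DUOX2 and its maturation factor DUOXA2, which produce hydrogen peroxide at epithelial surfaces (2.97 on the log2 scale each), KRT13 (3.91), the serine protease TMPRSS4 (4.27), CLCA4 (2.51) and the epithelial transcription factor GRHL3 (2.82). The antiviral gene OAS1 (3.23) and the hexokinase HK2 (2.95) passed too. Relative to each library's pan-fibroblast mean, 1203 genes passed and 1202 were lower in the transition zone, among them EDN2 (-3.25), TNC (-3.09), EDN1 (-3.26), MT1E (-3.07) and MSMB (-3.25), chosen after their values were seen. All 18 zone genes kept a positive difference, and the 1 gene that passed as higher was AC019349.1 (adjusted p 0.0453), which lies opposite to KRT13.

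LINC01082, the gene with the smallest p value, lies on chromosome 16 some 311 kb before FOXF1, a forkhead factor of visceral mesenchyme. FENDRR and LINC01081, on the opposite strand, begin 1.43 kb and 209 kb before it. FOXF1 stood at 11.5 ± 8.07 FPKM in the peripheral and 36.2 ± 13.5 in the transition zone (log2 difference 1.75, SE 0.49, limma adjusted p 0.217, higher in 4 of 4 donors), and FENDRR had a log2 difference of 2.58 (SE 0.53, adjusted p 0.0965). A hypothesis is that RNA of this region is more abundant for each fibroblast RNA in the transition zone. The mean change of FOXF1, FENDRR, LINC01082 and LINC01081 exceeded that of the pan-fibroblast genes by 0.72 on the log2 scale (SD 0.52), but LINC01082 was picked because it led the zone test. Without it the excess was 0.598 (SD 0.447, 4 of 4 donors, exact sign-flip permutation p = 0.125, two-sided, the smallest p that 4 donors allow). That is less than 2 SD, so more RNA of the region cannot be told apart from the fibroblast share with 4 donors. FOXF2, on chromosome 6, exceeded the pan-fibroblast genes by a mean of 0.0246 (SD 0.975), above in 2 of 4 donors.

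For the 18 zone genes, 4 of 100 splits of the 9 libraries into 5 and 4, drawn from 126 with the real one included, gave as many. The highest of the others gave 28. That share is under 0.05, but these splits take no account of the donor, so they cannot exclude chance in this paired design. For genes at an unadjusted p under 0.05 (1476), 9 of the 100 gave as many and the highest other 2097, so by that measure chance is not excluded either. The 3 other splits with as many all kept both replicate 4 libraries in 1 group, which points to that structure of the samples. The 16 splits that part all 4 donors are too few for a share under 0.05, and there the real one called 18 genes and the highest other 0. With the donor as a fixed block the real split called 0 (lowest limma adjusted p 0.0673, with 2291 genes at an unadjusted p under 0.05). For the 22 gene lists, 1 of the 100 splits, the real one, gave as many, and the highest of the others gave 21. Among the 16 that part all donors the highest other gave 21 lists too.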
